A study of Drosophila melanogaster with 8 samples.

How the data were processed

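RNA was sequenced from retinas dissected from female Drosophila melanogaster pupae 40 h after puparium formation, per the labels. There were 4 libraries of the w[1118] control stock and 4 of a stock carrying the sev[14] allele of sevenless with an unspecified w allele. Per the labels' protocols, RNA came from pooled retinas, was selected for polyadenylated transcripts and was read as paired ends on a MiSeq. No label says that the libraries of one genotype came from separate animals or days, so p-values here measure the spread between these libraries, which may be in part technical.

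The submitters' processing notes name FastQC 0.11.4, cutadapt 1.9.1, HISAT2 2.0.3, RSEM 1.2.31 and DESeq2 1.32.0, with the builds dm6 and BDGP6. The deposited table holds 15127 genes, of which 1547 were at 0 in every library. Its library columns hold a signal per gene, normalized counts that the authors made, which are gene counts divided by 1 factor per library. Each library's deposited values were whole multiples of the value of 1 read: between 99.98% and 100.0% of the values above 0 lay within 0.05 reads of a whole number, and the largest deviation was 0.0544 reads. The tolerance was set after the deviations had been seen. Recovered totals ranged from 13755813 to 19317307 reads per library. The authors' deposited log2 fold change was positive for genes higher in the sev14 columns, and the deposited score per gene and its p-value, adjusted over 13522 genes, were used only for comparison. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

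The columns were assigned to genotypes by the initial letters of their names, and they do not carry the replicate numbers of the sample titles. The control libraries are written W1, W2, W5 and W6 and the sev14 libraries S1, S2, S4 and S5, after the numbers in the column names. No 2 libraries of a genotype agreed within sampling noise: chi-square per degree of freedom between pairs ranged from 48.02 to 440.8. Of the 15127 gene identifiers, 14898 were found in the Ensembl BDGP6 annotation given for reference, and 98.6% of those had the same coordinates. Coordinates are those of the deposited table. Dates had replaced 5 gene symbols in the deposited values, and these were restored from the gene identifiers.

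Genes with a mean of at least 5 normalized counts over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with an intensity trend, 2-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2 scale, which understates the change of low genes. The level of sev was compared with an exact permutation test over 70 arrangements, 2-sided, whose smallest possible p is 0.02857. Lists of genes were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, over the 32 lists with at least 3 tested members. The test, its filter, the lists and the rule for named genes were fixed before the data were examined. The rule took sev, w, pros and the tested members of the R7 and cone cell lists; the 12 largest rises and the 12 largest falls among called genes whose libraries did not overlap and whose higher mean was at least 20; and up to 4 called members of every other list in order of p, or the 2 members with the largest change where none was called. Of 464 list entries, 455 were matched, and the rest were not analysed here. No gene of the mitochondrial genome was analysed here.

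The alternatives were TMM scaling, recomputed size factors, scaling by total reads, pseudocounts of 0.5 and 5, no filter and a filter of 20, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, array weights and leaving out each library. Alternatives chosen after seeing the data were a replicate block by column number and leaving out W6 and S4, or S2 and S5. Data for the sev14 against control comparison were simulated for the 10192 tested genes, each gene drawn independently of the others. The changed genes, 50 per fold, were taken only from genes with a mean of at least 20. In that setting the test recovered 8% of genes changed by 1.5-fold, 52% at 2-fold, 86% at 4-fold and 94% at 8-fold. It also called 9 unchanged genes, or 6.98% of the calls. Rates for lower genes, or for genes that vary together between libraries, were not simulated. Floors and counting intervals cover counting error only. Python 3.11.15 was used for reading the table and drawing.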

Results

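Polyadenylated RNA was measured in 8 libraries of female pupal retinas at 40 h after puparium formation. The control stock, w[1118], gave 4 libraries (W1, W2, W5 and W6), and the stock carrying sev[14] gave 4 (S1, S2, S4 and S5). The recovered totals were 17129012 reads in W1, 15102718 in W2, 14123264 in W5, 13755813 in W6, 15311491 in S1, 17084936 in S2, 19317307 in S4 and 18637922 in S5. Between 10235 and 12025 genes per library had a value above 0. The 9 ribosomal RNA pseudogenes took 12.5% of the reads in S2 and 10.1% in S5, against 0.528% to 3.67% in the other 6 libraries. Values below are normalized counts as mean ± SD over the 4 libraries of a genotype, and changes are log2 differences, sev14 minus control, with coordinates on BDGP6.

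The comparison asks which transcripts of the developing retina differ between the sev14 stock and the control stock. Every library of a genotype came from the same stock. An effect of sev therefore cannot be told apart from other differences between the stocks, for any gene below. The gene sev (FBgn0003366, X 11071441 to 11086299) encodes the receptor tyrosine kinase that the R7 precursor needs to become a photoreceptor, and without its signal that cell develops as a cone cell. Its own transcript stood at 298 ± 58.3 in control and 274 ± 137 in sev14 retinas. The difference of -0.26 was smaller than the spread between libraries (exact permutation p = 0.629, 2-sided). Without S4 the difference was 0.08 (exact permutation p = 0.8), and S4 held the lowest sev level, 119, against 202 to 416 in the other sev14 libraries.

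None of the 6 tested R7 genes passed the limma test, with 1 at an unadjusted p under 0.05, 0 called by edgeR and 0 by DESeq2. The transcription factor gene pros, active in R7 and in cone cells, averaged 3558 ± 1309 in control and 4278 ± 2265 in sev14 libraries (0.15, limma adjusted p = 0.931). The pros change was -0.19 without W6, -0.15 without S2 and -0.44 without S2 and S5. The others were ss, the selector of R7 subtype, at 52.9 ± 8.43 and 95.4 ± 39.4, dpr11 at 2429 ± 468 and 2526 ± 659, dve at 1511 ± 612 and 1800 ± 588, and run at 32.0 ± 19.7 and 22.4 ± 16.3. Of the 10 cone cell genes, 1 fell and 0 rose, and the same gene was called when adjusted over the list alone. It was wrapper (FBgn0025878, 2R 22379637 to 22382675), which encodes an immunoglobulin-family surface protein, at 1205 ± 143 in control and 714 ± 101 in sev14 retinas (-0.76, limma adjusted p = 0.0146, lower in 4 of 4 libraries). The adjusted p for wrapper was 0.0512 without W5, 0.0558 without W6 and S4, and 0.0532 without S2 and S5. The lens protein gene Crys (Cry in the deposited symbols) was at 3676 ± 1238 and 2022 ± 1422 (adjusted p = 0.228, but 0.0228 without S4, 0.0440 without W6 and S4, and 0.00352 with the replicate block by column number), while ct, sv, lz, B-H1, Sox14, cher and Eaat1 had adjusted p values of 0.667 or more.

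**Figure D1:**
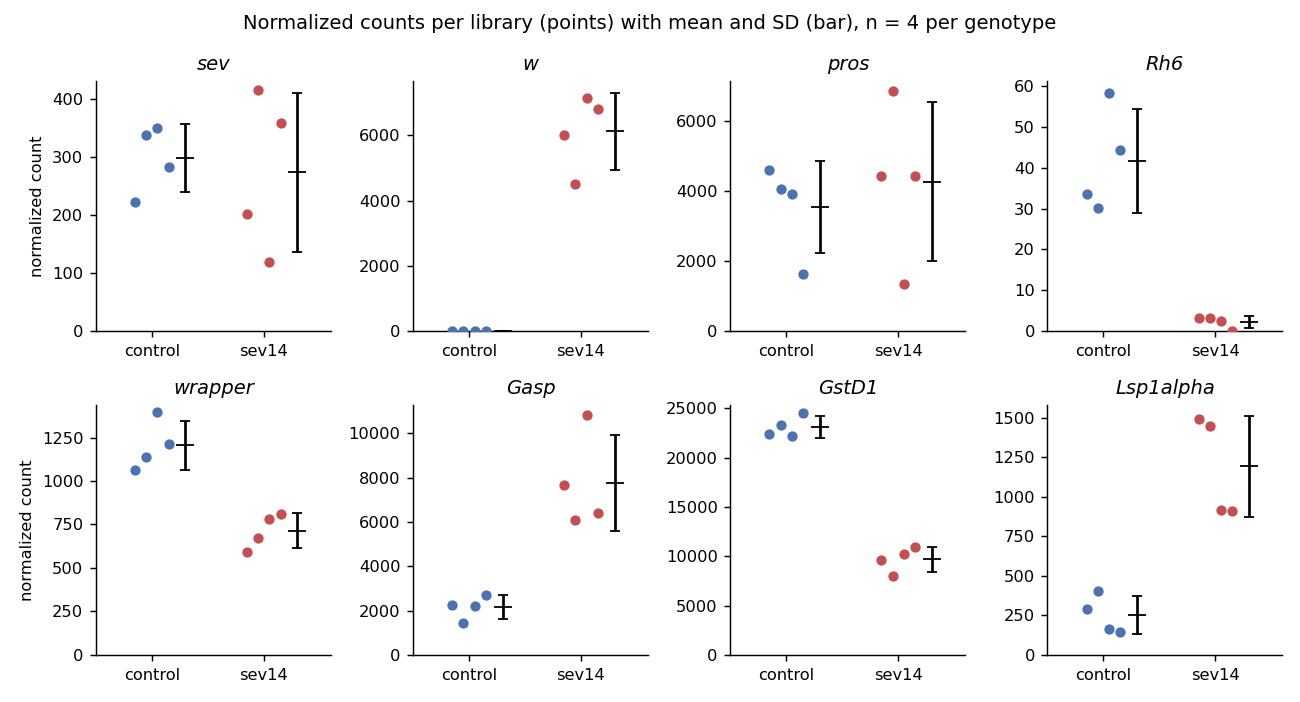
Each point is the normalized count of 1 library, for 8 genes, with control libraries in blue, sev14 libraries in red and bars for mean and SD (4 libraries per genotype). The sev points overlap between genotypes, and the w points lie at 5.60 to 14.4 in control libraries and 4506 to 7153 in sev14 libraries.

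Across the transcriptome, 243 genes rose and 186 fell in sev14 retinas, of 10192 tested, with 165 of the rises and 139 of the falls at least 2-fold. The white gene w (FBgn0003996, X 2790599 to 2796466), whose product carries eye pigment precursors, showed the largest rise among named genes, from 10.4 ± 3.88 to 6124 ± 1179 (9.12 ± 0.28 SE, limma adjusted p = 1.58e-07). The labels give the control stock a named w allele and the sev14 stock an unspecified w allele. The w difference may be that of the alleles, and is no evidence of an effect of sev. The antisense neighbours CR45600 and CG6912 rose by 8.62 and 8.08, mthl8, of the methuselah-like receptor family, by 7.89, and the adjacent CG32581 and CR44383 on X by 7.80 and 6.14. In the other direction Tektin-C, named for a protein of ciliary microtubules, went from 1773 ± 226 to 6.28 ± 3.33 (-8.09), and the cuticle protein gene Cpr49Ae from 1162 ± 495 to 7.46 ± 6.25 (-7.56). The cytochrome P450 gene Cyp6a17 had 897 reads in the control libraries and 1 in the sev14 libraries, a ratio of 949 with a 95% counting interval of 170 to 37537.

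Some of the largest changes were against libraries with no reads, where a fold is a bound set by a floor of 3 reads over the 4 libraries of a genotype, rounded here. Ada1-1 rose from 0 to 127 ± 12.5 (bound 165-fold), the cecropin gene CecB to 85.6 ± 40.4 (bound 111-fold), and the heat shock gene Hsp70Ba to 81.3 ± 29.0 (bound 105-fold). The dynein-related genes Sdic2 and Sdic3 went from 196 ± 82.5 and 101 ± 34.0 to 0 (bounds 268-fold and 138-fold). CG31278 and CG42537 went from 74.8 ± 17.5 and 75.4 ± 47.9 to 0 (bounds 102.5-fold and 103-fold). The remaining large rises were CR40469 (6.63), TotF of the Turandot stress family (6.81) and Muc14A (6.28, with adjusted p 0.0539 without S1 and 0.139 without S2 and S5). The remaining large falls were CG30428 (-7.46), CG32165 (-7.34), CR32011 (-7.34), the sodium channel family gene ppk13 (-6.17) and CG18853 (-5.64). Of the called genes whose higher mean was at least 20, 63 had a mean in 1 genotype under 5% of that in the other. There were 8 pairs of neighbours among these 63, and the stocks differ in w as well as in sev. Sdic and Hsp70 genes have near-identical copies, so reads may be shared between the copies of each.

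Of the 429 called genes, 425 had no overlap between the genotypes, and 11.1% of all tested genes had none, against 2.86% by chance. At an unadjusted p under 0.05 there were 1698 genes. The authors' deposited table called 545 genes higher and 372 lower, and 425 of the 429 were among them in the same direction. Scaling by total reads, which shifted the median gene by -0.14, gave 178 higher and 268 lower. The number that rose was 137 without S1, and the number that fell was 120 without W1, 116 without W2, 111 without W5 and 113 without W6. Without W6 and S4 there were 156 higher and 106 lower, and without S2 and S5 there were 145 higher and 138 lower.

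**Figure D2:**
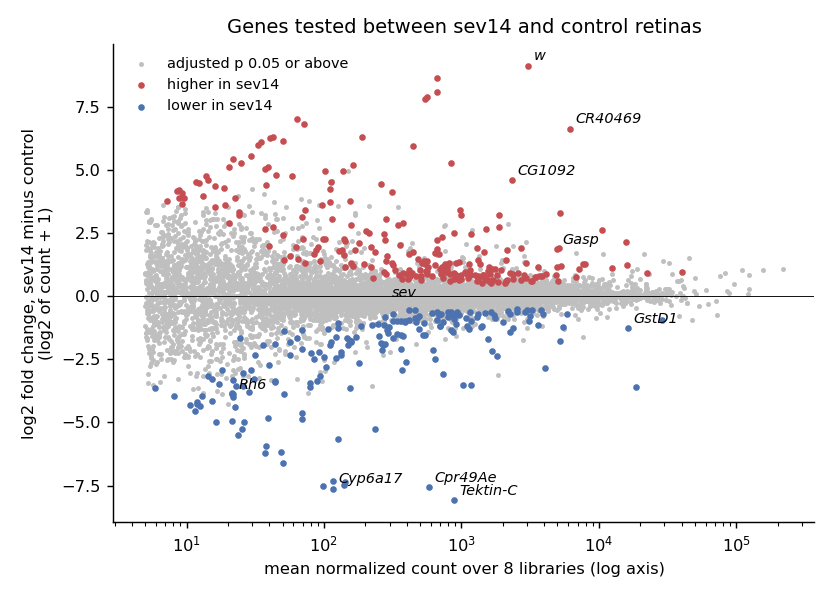
Each point is 1 tested gene, placed by its mean normalized count over the 8 libraries (log axis) and its log2 change, sev14 minus control, with the 243 higher genes in red and the 186 lower genes in blue. The gene w lies highest at 9.12, Tektin-C lies at -8.09, and sev lies near 0 at -0.26.

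Among photoreceptor genes, the R8 opsin gene Rh6 (FBgn0019940, 3R 15483158 to 15484699) fell from 41.6 ± 12.6 to 2.20 ± 1.51, with 160 reads in the control and 9 in the sev14 libraries (-3.89, limma adjusted p = 0.00754). It was the 1 called gene of 7 tested R8 genes, and was also called when adjusted over the list alone. Its adjusted p was 0.0774 with the replicate block by column number and 0.0548 without W6 and S4. Of 23 phototransduction genes, 2 rose and 1 fell, the same numbers as when adjusted over the list alone. The carotenoid uptake gene ninaD rose by 2.18 and the diacylglycerol kinase gene rdgA by 0.61, while the G protein subunit gene Galphaq went from 4491 ± 380 to 3093 ± 318 (-0.54). The vesicle fusion gene nSyb went from 3876 ± 308 to 2665 ± 391 (-0.55, limma adjusted p = 0.0489), as 1 of 16 photoreceptor and neuronal identity genes and 1 of 18 presynaptic genes, again alike over each list alone. These calls were close to the threshold: rdgA was lost without any 1 of the 8 libraries (adjusted p 0.0638 to 0.121) and under total-read scaling (0.104). Galphaq was lost without any library but S2 (0.0512 to 0.100), nSyb without W1, W2, W5, W6, S1 or S5 (0.0728 to 0.136), and ninaD without W2, W5 or S1 (0.0600 to 0.0771).

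Of 15 genes of the corneal lens and of chitin, 3 rose and 1 fell, or 8 and 3 adjusted over the list alone. The list shares serp and verm with the tracheal list, whose median change was 1.61. The chitin-binding protein gene Gasp (FBgn0026077, 3R 6088799 to 6100887) rose from 2148 ± 534 to 7734 ± 2168 (1.85, limma adjusted p = 0.00141), the cuticle gene Cpr66D by 1.23 and the chitin organiser knk by 0.66, and the lens gene retinin fell from 158 ± 45.8 to 21.2 ± 19.6 (-3.37). The list's median change was 0.66, with adjusted p = 0.0367 by limma's camera and adjusted p = 0.875 with an estimated correlation. Its adjusted p was 0.0673 without W2, 0.0703 without S1 and 0.187 without S4. Cpr66D was not called without W1, W2, W5, S1, S2 or S4 (adjusted p 0.0756 to 0.125), knk without W1, W2, W5, S1 or S4 (0.0812 to 0.125), or retinin without W1, W2, W5, W6 or S2 (0.0502 to 0.0814). Under total-read scaling the adjusted p was 0.138 for knk and 0.0759 for Cpr66D.

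Eye pigment genes included 2 rises and 0 falls among 22 tested, with the same count over the list alone. These were w, in which the stocks themselves differ, and cn, the kynurenine hydroxylase gene of the brown pigment pathway, which went from 3064 ± 847 to 6913 ± 1986 (1.17, limma adjusted p = 0.0208). The call for cn ended without W1, W2, W5, S1 or S5 (adjusted p 0.0512 to 0.0701). Of the 17 pigment cell and interommatidial genes 1 fell, or 2 adjusted over the list alone: the cell death gene grim, from 408 ± 32.9 to 170 ± 64.1 (-1.32, limma adjusted p = 0.0132, and 0.0661 without W6 and S4). Of the 30 genes of Sevenless and EGFR signalling 1 fell, and the same number over the list alone: csw, a phosphatase that acts downstream of the Sevenless receptor, from 4877 ± 191 to 3006 ± 705 (-0.73, limma adjusted p = 0.0339). It was not called without W1, W2, W5, W6, S1, S4 or S5 (adjusted p 0.0529 to 0.0973).

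Markers of other cells that a dissected retina could hold were tested as lists. Of 10 fat body genes, 1 rose and 0 fell, or 4 and 1 adjusted over the list alone, and the larval serum protein gene Lsp1alpha (FBgn0002562, X 12490291 to 12492982) went from 252 ± 122 to 1192 ± 320 (2.33, limma adjusted p = 0.00299). The fat body list's median change was 0.70 (adjusted p = 0.0440 by limma's camera, and adjusted p = 0.875 with an estimated correlation). Its adjusted p was 0.0846 without W5, 0.0701 without W6 and 0.0995 without S1. Of 12 glial genes 2 fell, or 1 rose and 4 fell over the list alone: wrapper, which the cone cell list also holds, and Mdr65, a transporter of the blood-brain barrier, from 7226 ± 1440 to 4426 ± 435 (-0.69). Mdr65 was not called without W1, W5, W6, S1, S2, S4 or S5 (adjusted p 0.0582 to 0.117). None of 7 tracheal genes passed the limma test (median 1.61, limma's camera adjusted p = 0.0615), with 5 at an unadjusted p under 0.05, 2 called by edgeR, 4 by DESeq2, and 4 rises and 1 fall adjusted over the list alone. Of these genes, serp and verm are also in the corneal lens and chitin list, so the changes of both lists are not separate results. The tracheal list passed with TMM scaling (adjusted p 0.0479), total-read scaling (0.00670), a pseudocount of 5 (0.0465), no filter (0.0474), without W5 (0.0360), without S5 (0.00310) and without S2 and S5 (0.00697). With an estimated correlation its adjusted p was 0.875, and its receptor gene btl was at 22.02 ± 9.95 and 97.0 ± 64.4 (adjusted p = 0.177, but 0.0345 without S5, 0.0161 by DESeq2 and 0.00618 in the authors' values).

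Optic lobe and brain neuron markers varied between libraries of 1 genotype. Their per-library level, the mean log2 deviation of 13 markers, was 0.52 in W1, 0.81 in W2, -0.15 in W5 and -0.69 in W6, and 0.06 in S1, 1.07 in S2, -1.19 in S4 and -0.43 in S5. The vesicular glutamate transporter gene VGlut had 2792 normalized counts in S2 and 669 in S4. No member was called by limma, with 0 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2. Neural lists moved with these libraries: without S2, the presynaptic list was lower with an adjusted p of 0.00591, the dpr family with 0.0119, the DIP family with 0.0190, the glial list with 0.0190, and the axon targeting and optic lobe lists with 0.0232 each. Without S4, the library at the other extreme, the axon targeting and optic lobe lists turned to the higher direction. Without S2 the eye pigment list was also past the test, higher, with an adjusted p of 0.0157, a median change of 0.0898 and 2 called members. The eye pigment list holds w, in which the stocks themselves differ. With an estimated correlation, 0 of the 32 lists passed without S2, where 9 did with the preset one.

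**Figure D3:**
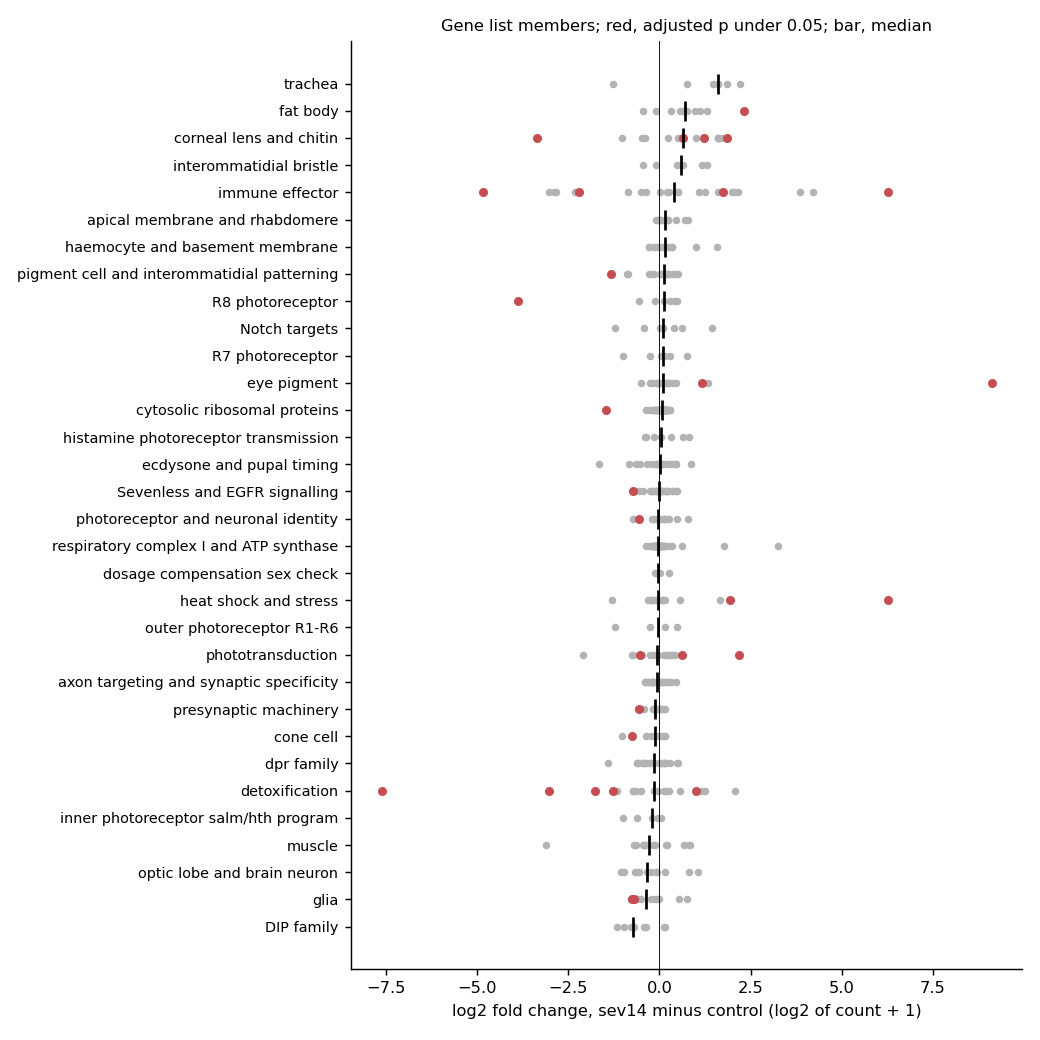
Each point is the log2 change, sev14 minus control, of 1 tested member of a gene list, red where the adjusted p was under 0.05, and the bar is the median of the list. The corneal lens and chitin list has a median of 0.66, the fat body list 0.70 and the trachea list 1.61.

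Defence and stress genes moved in both directions. Of 19 detoxification genes, 1 rose and 4 fell, or 2 and 4 adjusted over the list alone. The glutathione transferase gene GstD1 (FBgn0001149, 3R 12367817 to 12369268) fell from 23090 ± 1085 to 9696 ± 1246 (-1.26, limma adjusted p = 0.00101), as did GstE1 (-1.76), Cyp6a17 (-7.62) and the P450 gene Cyp4p1 (-3.03), which was named outside the rule after its value was seen. The neighbouring GstE6 rose by 1.02, and was not called without W5, W6, S1 or S2 (adjusted p 0.0635 to 0.0839) or under total-read scaling (0.0582). Of 24 immune effector genes, 2 rose and 2 fell, or 6 and 4 adjusted over the list alone: CecB and PGRP-LB, which encodes a peptidoglycan amidase, went up (PGRP-LB by 1.76), and the attacin gene AttD and the bomanin gene IM3 went down (-2.21 and -4.84). The adjusted p for AttD was 0.0547 without S2 and S5. IM3 was not called without W1, W2, W6, S2, S4 or S5 (adjusted p 0.0548 to 0.0970), nor in the authors' table. Of 17 heat shock and stress genes 2 rose and 0 fell, or 3 and 0 over the list alone, Hsp70Ba and Hsp70Bbb, the latter from 87.4 ± 44.9 to 354 ± 194 (1.95, and adjusted p 0.0823 to 0.108 without W1, W5, W6, S1 or S2). Of 85 cytosolic ribosomal protein genes 1 fell, and 1 over the list alone: RpS5b, from 428 ± 71.8 to 157 ± 39.0 (-1.46, limma adjusted p = 0.00330).

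In 17 of the 32 lists limma called no member. Together these held 223 members, of which 22 had an unadjusted p under 0.05, 2 were called by edgeR and 9 by DESeq2. Besides the R7, optic lobe and tracheal lists they were the outer photoreceptor, salm and hth program, apical membrane, histamine transmission, axon targeting, dpr, DIP, Notch target, bristle, haemocyte, muscle, dosage compensation, ecdysone and respiratory chain lists, none of which had a member called over the list alone except the Notch target list, with 1 lower. That gene was the Notch target E(spl)m3-HLH, at 819 ± 114 and 380 ± 166 (adjusted p = 0.0584, but 0.0340, 0.0476 and 0.0499 without S4, S5 and S2, 0.0258 with the replicate block by column number, 0.0381 with total-read scaling, 0.0261 with array weights, 0.00963 by DESeq2 and 0.00133 in the authors' deposited values). In the dpr family dpr21 (CG42596 in the deposited symbols) was at 842 ± 420 and 306 ± 135 (adjusted p = 0.0692, but 0.0305 without S2, 0.00511 with the replicate block, 0.0410 with total-read scaling, 0.00420 by DESeq2 and 0.0309 in the authors' deposited values). The other members with the largest changes in these lists were ro (-1.21) and B-H2 (0.49), salr (-1.01, and adjusted p 0.0143 in the authors' values) and salm (-0.60), chp (0.79) and baz (0.70, and adjusted p 0.0237 in the authors' values), ort (0.80) and Hdc (0.66), Toll-7 (0.45) and side (-0.41). They were also dpr3 (-0.63), DIP-eta (CG14010, -1.17) and DIP-beta (CG42343, -0.98), Tom (1.43), nompC (1.31) and nompB (1.18), eater (1.57) and Hml (1.01, and adjusted p 0.0444 without W2), hbn (-1.06) and Gad1 (1.06), Act88F (-3.11, with 12584 in W5 against 52.2 to 1484 in the other control libraries, and adjusted p 0.0101 by DESeq2) and sls (0.83), and dysf (dys, 2.21). The dosage compensation pair was dsx (0.25) and Sxl (-0.12), the ecdysone pair Hr38 (-1.66, with 499 in W5 against 3.01 to 39.8 in the other control libraries) and ftz-f1 (0.87), and the respiratory pair ND-51L1 (CG11423, 3.24, adjusted p 0.0972, but 0.0308 without S4, 0.0448 without W6 and S4, 0.0293 with the replicate block, 0.00223 by DESeq2 and 0.00118 in the authors' values) and ATPsynepsilonL (CG31477, 1.76). The yolk genes Yp2 and Yp3, the 2 tested members of the ovary and yolk list, had changes of -0.39 and -0.03.

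By limma's camera, the corneal lens and chitin list and the fat body list were the 2 of 32 past the threshold, and the others had adjusted p values from 0.0615 to 0.906; with an estimated correlation none passed. Of the 35 splits of the 8 libraries into 4 and 4, 32 gave at least 2 lists with the preset correlation. By fry, which tests whether a list's own genes move one way on balance, the detoxification list was lower with an adjusted p of 0.0422, though 8 of its 19 genes were higher. By fry's mixed test, of change in either direction, adjusted p was 2.93e-07 for detoxification and eye pigment, 1.10e-06 for heat shock and 3.66e-06 for immune effector. It was 0.000234 for corneal lens and chitin, 0.000480 for R8, 0.000863 for pigment cell, 0.00321 for glia and 0.00711 for phototransduction. It was 0.0163 for trachea, 0.0241 for Sevenless and EGFR, 0.0329 for fat body and 0.0502 or more for the rest. A few genes can carry it. The median, the mean and the camera test differed in sign for the R7, R8, photoreceptor identity, histamine, pigment cell and interommatidial, Sevenless and EGFR, ecdysone, heat shock and respiratory lists. Under total-read scaling the median changed sign for the R7, R8, histamine, pigment cell and interommatidial, eye pigment, Sevenless and EGFR, Notch, ecdysone and ribosomal lists.

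A family chosen after its values were seen, the Osiris genes of transmembrane proteins, had 4 rises and 0 falls among 18 tested members. Osi21 on 2L rose from 191 ± 57.4 to 1785 ± 514 (3.21), Osi6 by 2.13, Osi1 by 0.97 and Osi24 by 0.82. The family's adjusted p over 41 families was 1.02e-06 by limma's camera and 0.754 with an estimated correlation, and 0.0607 by Fisher's exact test on the called members. The family's median change was 0.79, and 0.64 under total-read scaling, and its genes were not recomputed under the alternatives other than scaling. A segment of 3R from 6173549 to 6327308 holds 16 of them, with a median change of 0.79, beside 5 other tested genes with a median of 0.52 and none called by limma.

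**Figure D4:**
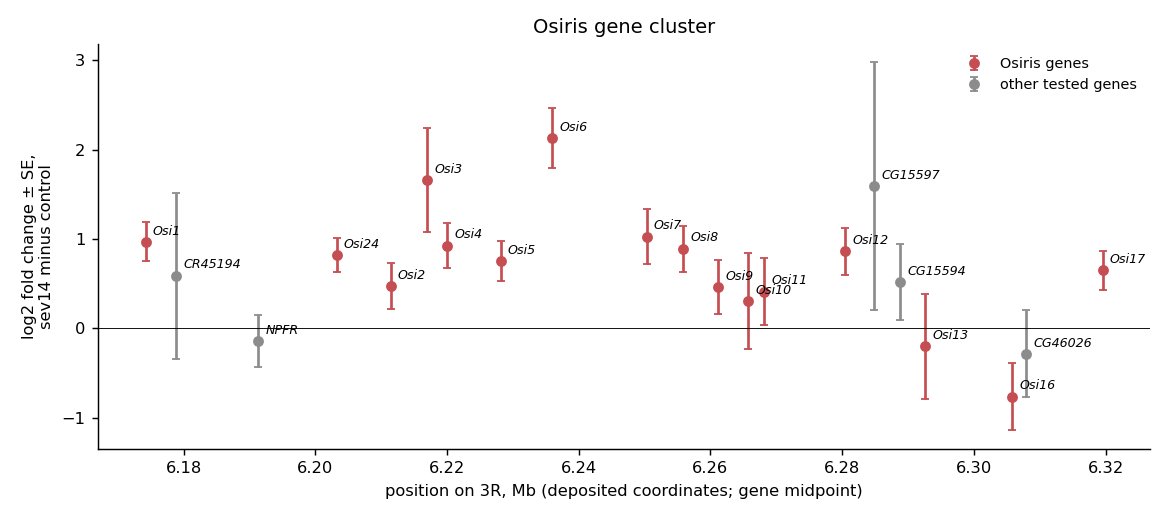
Each point is the log2 change ± SE, sev14 minus control, of 1 tested gene of the 3R segment, placed by its midpoint, with 16 Osiris genes in red and 5 other genes in grey. Osi6 lies highest at 2.13, and Osi16 lies lowest at -0.76.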

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

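The tests of optic lobe tissue and of long transcripts were chosen after the result was seen; the comparison of single libraries with the rest of their genotype was fixed before. In each of 196 groups of 4 libraries the highest and the lowest library were compared with the others, and 18 stood apart. In 6 of these the other 3 libraries were at 0, where any read sets a library apart by construction. Among the 183 groups with at most 2 libraries at 0, 12 stood apart, where chance gives 9.15.

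Among control libraries, W2 stood apart for Eaat1 with 2014 normalized counts against 1231 to 1272 in the others, rdgA with 3122 against 4248 to 4359, Hml with 188 against 72.1 to 82.9, Hsp70Bbb with 154 against 54.4 to 70.8 and PGRP-LB with 83.4 against 107 to 111. W1 stood apart for grim with 457 against 388 to 396, Sxl with 5088 against 4566 to 4602, and TotF with 0.885, which is 1 read, against 0. W5 stood apart for the flight muscle actin gene Act88F with 12584 against 52.2 to 1484, and for Hr38 with 499 against 3.01 to 39.8. Among sev14 libraries, S4 stood apart for mthl8 with 922 against 1177 to 1213 and for Cyp6a17 with 0.818, 1 read, against 0. S5 stood apart for ftz-f1 with 492 against 133 to 177, CG30428 with 4.77 against 0 and CR32011 with 2.86 against 0. S1 stood apart for ppk13 with 2.15 against 0 and IM3 with 6.45 against 0, and S2 for ort with 510 against 9.54 to 62.3.

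The ort value in S2 goes with a wider pattern: optic lobe and brain neuron markers differed between libraries of the same genotype, from -1.19 in S4 to 1.07 in S2 on the log2 scale. Loss of long transcripts cannot be decided here, since span is the genomic distance from start to end with introns, not transcript length. The 4 markers that span under 10 kb varied with an SD of 0.950 within genotypes, against 0.229 for 996 genes spanning over 20 kb. That SD was above 99.9% of 10000 random sets of 4 genes of short span. The level of the genes of long span was also highest in S2 (0.35) and lowest in S4 (-0.32). Carried-over optic lobe tissue may account for the differences in these markers: over 8 libraries the level of the DIP family followed that of the markers. Pearson r was 0.965 (exact permutation p = 0.000322), Spearman rho was 0.976 (exact permutation p = 0.000397), and r was 0.958 without the 2 farthest libraries. With levels centred by genotype r was 0.980 (exact permutation p = 0.00347 within genotypes), and 0.963 without the 2 farthest libraries. With that centring rho was 1 (exact permutation p = 0.00347, the smallest that rho can give). Of the 13 markers 3 are in another list, the most abundant were VGlut with 2792 in S2 and 669 in S4, dac with 1874 and 722, ey, which did not follow, with 998 and 1021, and VAChT with 1846 and 427. The 4 short markers include ort, which raised the pattern, and bsh, which ranged only from 239 to 393. A median of 996 genes also varies less than a median of 4. Genes of the retina lists also differed between these libraries, in both directions. In S2 and S4, pros had 6875 and 1347 and ct 6727 and 1459, while chp ran the other way with 15309 and 34176. Developing neurons of the retina itself that differ between libraries would give the same relation, which therefore does not single out optic lobe tissue. No biological explanation was tested.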

How the results depend on the processing

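The replicate block by column number and the removal of W6 and S4, or of S2 and S5, were chosen after the data had been seen; all other alternatives were fixed before. The planned block by the replicate numbers of the sample titles was not run, because the columns carry other numbers and do not show which libraries were prepared together. The block by column number used the 6 libraries of W1, W2, W5, S1, S2 and S5. Of the 95 named genes 47 were called, 29 of these under every setting, and no called gene changed direction. Most of the called genes had no overlap between genotypes, so leaving out libraries, also for the block, could not have turned them. Among 2082 values of named genes under alternatives, 45 of genes that were not called changed sign. Of 527 genes averaging 20 to 40 reads, between 10 (S2) and 61 (W1) were at 0 in a library, which did not follow depth (17084936 reads in S2 and 17129012 in W1).

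The main counts of 243 higher and 186 lower became 239 and 196 with TMM scaling, 242 and 186 with recomputed size factors, 178 and 268 with total reads, 234 and 178 with a pseudocount of 0.5, 261 and 194 with 5, 235 and 169 with no filter, 218 and 159 with a filter of 20, 228 and 156 with edgeR and 297 and 207 with array weights. DESeq2 gave 503 and 344, and the authors' deposited values gave 545 and 372; the cause was not tested. With the replicate block they were 197 and 131. Without W6 and S4 they were 156 and 106, and without S2 and S5 145 and 138, with 6 libraries in place of 8. Leaving out each library in turn gave 137 to 251 higher and 111 to 189 lower, with fewer libraries each time.

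The 2 lists past the camera test became 1 with the replicate block, 1 without W6 and S4, 10 without S2 and S5, 1 with array weights and 0 with an estimated correlation; leaving out each library gave 0 to 9. The other settings gave 2 or 3. The cause was not tested. The corneal lens and chitin list had an adjusted p of 0.0771 with the replicate block, 0.116 without W6 and S4 and 0.0546 with array weights, in a range of 0.000604 to 0.875 over all alternatives; the fat body list had 0.0556 without S2 and S5, in a range of 0.000118 to 0.875. The trachea list, which missed the threshold with 0.0615, passed with TMM scaling (0.0479), total reads (0.00670), a pseudocount of 5 (0.0465), no filter (0.0474) and without S2 and S5 (0.00697), and had 0.875 with an estimated correlation.

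Lists whose direction changed had these adjusted p values, and the cause was not tested. With total-read scaling the histamine list had 0.871 and the muscle list 0.825. The Notch list had 0.569 with no filter and 0.921 with a filter of 20, where the outer photoreceptor list also had 0.921. With the replicate block the R8, photoreceptor identity, histamine and pigment cell lists each had 0.992 and the heat shock list 0.824. Without W6 and S4 the R8 and photoreceptor identity lists had 0.962 and the heat shock list 0.951. Without S2 and S5 the R7 list had 0.492, the outer photoreceptor list 0.765, the histamine list 0.552, the muscle list 0.754, the ecdysone list 0.375 and the respiratory list 0.171.

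Leaving out each library turned the direction of 17 lists at least once, with adjusted p ranges of 0.666 to 0.990 for R8 (without W1 or W6), 0.666 to 0.989 for photoreceptor identity (W1, S1, S4), 0.661 to 0.991 for pigment cell (W1, S1, S4), 0.0701 to 0.924 for muscle (W1, W5, S4, S5), 0.684 to 0.989 for dosage compensation (W1, S4), 0.0763 to 0.957 for ribosomal (W1, S1), 0.694 to 0.981 for ecdysone (W2, W6, S2, S5) and 0.370 to 0.988 for respiratory (W2, W6, S2, S5). The others were 0.8286 to 0.991 for outer photoreceptor (W5, W6, S2), 0.584 to 0.988 for Sevenless and EGFR (W5, S1), 0.629 to 0.990 for phototransduction (W6), 0.8286 to 0.996 for histamine (W6, S2), 0.299 to 0.989 for immune effector (S1), 0.540 to 0.957 for R7 (S2), 0.0232 to 0.989 for axon targeting (S4), 0.0232 to 0.986 for optic lobe (S4) and 0.367 to 0.898 for heat shock (S4).

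Calls of named genes lost under a setting other than leaving out 1 library had these adjusted p values. With the replicate block 8 were lost (Rh6, nSyb, Galphaq, rdgA, knk, Cpr66D, csw and Mdr65, 0.0523 to 0.146). Without W6 and S4 14 were lost (those 8 with wrapper, ninaD, grim, Hsp70Bbb, IM3 and GstE6, 0.0548 to 0.137). Without S2 and S5 11 were lost (wrapper, Muc14A, nSyb, ninaD, Galphaq, rdgA, Mdr65, Hsp70Bbb, AttD, IM3 and GstE6, 0.0532 to 0.230). No filter lost nSyb, rdgA, Cpr66D and Mdr65 (0.0544 to 0.0634), a filter of 20 nSyb, rdgA and IM3 (0.0517 each), edgeR nSyb, rdgA, knk and IM3 (0.0558 to 0.0639), total-read scaling rdgA, knk, Cpr66D and GstE6 (0.0582 to 0.138), a pseudocount of 0.5 rdgA (0.0508), array weights rdgA and IM3 (0.0517 and 0.0660) and the authors' values IM3 (0.0664).

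Named genes not called in the main test passed as follows. The replicate block gained 4 (Cry 0.00352, CG42596 0.00511, E(spl)m3-HLH 0.0258 and CG11423 0.0293) and the removal of W6 and S4 gained 2 (Cry 0.0440 and CG11423 0.0448). DESeq2 gained 5 (CG42596, E(spl)m3-HLH, Act88F, btl and CG11423, 0.00223 to 0.0161) and the authors' values 6 (salr, baz, CG42596, E(spl)m3-HLH, btl and CG11423, 0.00118 to 0.0309). Total-read scaling gained 2 (CG42596 0.0410 and E(spl)m3-HLH 0.0381) and array weights 1 (E(spl)m3-HLH 0.0261).

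Among genes that were not called, the log2 change turned as follows; the cause was not tested. With the replicate block and without W6 and S4, sev was 0.0653 (exact permutation p = 0.75 for the block), run 0.31, ct 0.0417 and Yp3 0.42. With total-read scaling Sox14 was -0.0617 and dpr11 -0.10. With DESeq2 and the authors' table ct was 0.0102 and 0.0104, lz 0.0537 and 0.0540 and Yp2 0.26 and 0.26, and with edgeR lz was 0.0410 and Yp2 0.25. Without S2 and S5 pros was -0.44, dpr11 -0.00937, lz 0.0110 and Yp2 0.64. Leaving out each library gave ranges of -0.51 to 0.0828 for sev, -1.67 to 0.22 for run, -0.51 to 0.00448 for Eaat1 and -0.00975 to 0.35 for B-H1, which turned without S4. They were -0.23 to 0.0642 for sv, turned without S2, -0.0556 to 0.22 for Sox14 (W6), -0.19 to 0.63 for pros (W6, S2), -0.43 to 0.31 for ct (W2, S4), -0.11 to 0.16 for dpr11 (W1, W5, S2) and -0.16 to 0.16 for lz (W5, W6, S1, S2). For ort it was -0.36 to 1.51 (S2), for Yp2 -1.05 to 0.70 (S5) and for Yp3 -0.58 to 0.28 (W5, W6, S2, S4).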

Other observations

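The family tests and the tests of X segment, stock sequence, segment copy, trachea and pupal age were chosen after the result was seen; the counts over other splits of the libraries were fixed before. The genes named here outside the rule were chosen after their values were seen, and they were not recomputed under the alternatives. Over 41 families of genes sharing a symbol stem, called genes were more frequent among the GstE glutathione transferases (Fisher's exact adjusted p = 0.0331), the Cpr cuticle proteins (0.0331) and the cadherin genes with the stem Cad (0.0484). With an estimated correlation, limma's camera gave adjusted p = 0.995 for each of the 3. Of 31 Cpr genes 4 rose and 2 fell, with a median of 1.00: Cpr97Ea rose from 484 ± 110 to 3274 ± 1114, Cpr92A by 5.56 and Cpr49Ac by 1.77, and Cpr64Aa fell by 3.89. Of 11 GstE genes 3 rose and 1 fell, with GstE14 going from 170 ± 53.0 to 1773 ± 294. Of 8 genes with the stem Cad 3 rose and 0 fell, Cad88C by 3.21, Cad99C by 0.74 and Cad86C by 0.64. This stem leaves out other cadherin genes, such as CadN and shg, which were not called.

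Sweet taste receptor genes of the Gr64 cluster on 3L had no reads in the control libraries: Gr64a averaged 43.3 ± 11.3, Gr64c 66.1 ± 23.8, Gr64b 17.7 ± 11.2 and Gr64e 24.6 ± 13.4 in sev14 libraries. Other rises outside the lists were the odorant-binding protein gene Obp99a, from 403 ± 89.9 to 2618 ± 744, and the chitinase gene Cht6 by 1.19, with the bristle and epidermal genes jv by 0.80 and grh by 0.84. The long noncoding RNA roX1, which is abundant in males, was at 36.7 ± 7.48 and 38.9 ± 15.4. The gene CR41509, placed on Y, averaged 21.2 in control and 0 in sev14 libraries (limma adjusted p = 0.0131), and the cause was not tested.

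Of the 35 splits of the 8 libraries into 4 and 4, only the genotype split gave as many as its 429 called genes. The highest other gave 1. Splits that mix the genotypes hold the genotype difference as spread within each side, which lowers their counts. The genotype split ranked first, but 1 of 35 is the smallest share these splits can give, so they do not exclude chance. For gene lists, 32 of the 35 splits gave at least the 2 lists of the genotypes and the highest other gave 13, so chance cannot be excluded for the list calls. With an estimated correlation, 0 of the 35 splits gave a list.

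Called genes whose higher mean was at least 20 were considered. In 63 of them, 35 higher and 28 lower in sev14, the mean of 1 genotype was under 5% of that of the other. An X segment carried along with sev is argued against as the whole cause, since 15.9% of them lie on X (10 genes, exact 95% interval 7.88% to 27.3%), where 16.6% of all tested genes lie. Of these genes 8 pairs were neighbours, against a median of 0 in 10000 shuffles (one-sided permutation p = 1e-04, the smallest they can give), which sequence differences between the stocks or co-regulated neighbours could give. Stock and sev genotype fall on the same libraries, so sequence differences between the stocks and an effect of sev cannot be told apart for these genes or for any other called gene.

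Of 18 Osiris genes 4 rose and 0 fell past the limma test, while Osi13 (-0.20) and Osi16 (-0.76) were lower, and the family's adjusted p was 1.02e-06 by limma's camera but 0.754 with an estimated correlation, and 0.0607 by Fisher's exact test, so a rise of the whole family is not shown; 3 technical or sampling explanations of the values were weighed. An extra copy of the 3R segment stays open for the genes inside it, where the 5 other genes had a median of 0.52, from -0.29 to 1.59 with none called by limma; it does not reach the 2 Osiris genes outside, Osi21 on 2L, which rose by 3.21, and Osi22, at 0.43 (adjusted p = 0.283). More tracheal tissue in the sev14 samples cannot be told apart from a change in the retina, since the trachea list had an adjusted p of 0.0615, from 0.00310 to 0.195 over the other settings with the preset correlation, and 0.875 with an estimated one. A different pupal age cannot be told apart either: 0 of 20 ecdysone and timing genes passed the limma test, with 3 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2, and the members go both ways with age. The sev genotype, carried by the same libraries, was not tested apart from these.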
